A study of Mus musculus with 12 samples.

How the data were processed

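Total RNA of the anterior prostate was hybridised, per the labels, to Affymetrix GeneChip Mouse Gene 1.0 ST arrays, which read whole transcripts through probe sets called transcript clusters. Per the design text of the series, equal amounts of RNA from 2 mice were combined for each array, so a replicate is a pool of 2 mice and p-values measure the spread between pools. The 12 arrays are 4 APT121 pools and 8 wild type pools, named here by the replicate numbers of their labels. Tissue was frozen at collection and RNA was purified on columns with DNase treatment, per the labels.

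The deposited table holds 1 intensity per transcript cluster and array on a linear scale, which the authors made by RMA (background correction, quantile normalisation between arrays and summarisation of probes), per the submitters' processing notes. The software and its version are not given in the sources used here. RMA ties the value distributions of all arrays together, so a change of total RNA per cell would not be seen. The median of an array's values ran from 32.1 to 33.7, and 0 values were missing. Arrays give no read depth, and detection calls were not used here, so the number of arrays limits the precision.

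Log2 of the deposited values was taken here. Of 28815 transcript clusters, 21780 had 1 gene symbol in the platform annotation, 1605 had several and 5430 had none. The gene IDs of 21689 of the clusters with 1 symbol were found in the RefSeq gene table, and 0 symbols were updated. Clusters with several symbols or none were left out of the gene tests. For 998 genes with more than 1 cluster, the cluster with the highest mean over all arrays was used, which left 19935 genes. No filter on low values was applied. No genome build is named for the values, so no coordinates are given.

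Genotypes were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, genotype as the only term, all 12 arrays, two-sided), with Benjamini-Hochberg adjustment and a threshold of 0.05. The design text of the series names SAM at a 5% false discovery rate, and a SAM-type statistic with 100 permuted groupings, written for this work, was run as an alternative. On simulated data for this comparison (19935 genes), limma recovered 80.9% of the genes changed by 0.5 on the log2 scale, 98.5% of those changed by 1 and 100% of those changed by 2, with 4.62% false among 195 calls. The SAM-type statistic recovered 33.8%, 90.9% and 100% of them and made 150 calls with 0.667% false. In the simulation 68, 66 and 66 genes were changed by 0.5, 1 and 2, and noise was drawn independently for each gene. Far more genes (10527) were called in the real data, whose genes vary together, so these rates need not hold there.

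Before the data were examined, 30 gene lists were fixed (17 pathways or gene classes and 13 sets of cell type markers) with 775 members, of which 715 were measured. The other members and the T121 transgene are not analysed here. The pathway lists were DNA replication and E2F targets, mitosis, pRb pathway and cell cycle entry, p53 targets, apoptosis, DNA damage response and repair, androgen-regulated genes, prostate secretory proteins, secretory pathway and unfolded protein response, glycolysis, oxidative phosphorylation, lipid and cholesterol synthesis, polyamine, citrate and zinc metabolism, vitamin D signalling, interferon response, immediate early and heat shock genes, and genes known to differ between C57BL/6J and DBA/2. The marker lists were luminal epithelium, basal epithelium, neuroendocrine cells, smooth muscle, fibroblasts and extracellular matrix, endothelium, myeloid cells, lymphocytes, antigen presentation by MHC class II, seminal vesicle, adipose tissue, skeletal muscle and peripheral nerve. Lists were tested with camera of limma at its preset inter-gene correlation of 0.01, adjusted over the 30 lists, and again with an estimated correlation, with fry and, as chosen after seeing the data, with an exact permutation test of the list median.

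Genes were named by a rule fixed in advance. It took the 10 largest rises and the 10 largest falls among genes past the threshold whose APT121 values all lay above or all below the wild type values (predicted genes, noncoding RNAs and olfactory receptors excepted), up to 3 members of each list past the threshold with the largest absolute difference, and a set of genes always named (of which Rb1, Rbl1, Rbl2, Cdkn2a, Mki67, Pcna, Pbsn, Krt5, Krt8, Acta2 and Vdr are analysed here). This gave 111 genes. Further list members named in the text were chosen after their values were seen.

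Alternatives fixed before the data were examined were median centring and repeated quantile normalisation over the genes tested, leaving out the 25% or 50% of genes with the lowest mean over all arrays, eBayes with trend and robust options, array weights, the mean of a gene's clusters, replicate number as a block, wild type arrays 1 to 4 alone, leaving out each array in turn, a 1.5-fold minimum, and exact permutation tests of the named genes over the 495 splits of the arrays. Wild type arrays 5 to 8 alone and the omission of wild type arrays 5, 6 and 7 were added after seeing the data. Gene order along chromosomes came from the RefSeq gene table of assembly GRCm38.p6. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15, with numpy 2.4.6 and pandas 2.3.3.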

Results

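Gene expression in the anterior prostate, a pair of lobes of the mouse prostate that lie along the seminal vesicles, was compared between APT121 and wild type males. APT121 mice carry T121, a fragment of SV40 large T antigen that binds and inactivates the pRb family of proteins, under the control of the prostate-specific probasin promoter, and the study concerns their prostatic intraepithelial neoplasia (PIN) lesions. The mice were 12 weeks old, had eaten the semi-purified AIN93G diet since 3 weeks of age and came from the F3 generation of a C57BL/6J and DBA/2 cross. RNA of 2 mice was pooled for each array, so that 24 mice gave 4 APT121 arrays (8 mice) and 8 wild type arrays (16 mice). The median intensity of an array lay between 32.1 and 33.7 and the highest between 18323 and 20612. The number of arrays limits the precision. Below, means are of log2 intensities ± SD over 4 APT121 and 8 wild type arrays, differences are APT121 minus wild type on the log2 scale ± SE, and adjusted p-values are from limma.

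The comparison of the genotypes asks which transcripts differ in prostate that carries PIN lesions. APT121 prostate had higher transcripts of cell division. All 50 measured genes of DNA replication and E2F targets rose, with a median difference of 2.49, and 58 of the 60 measured mitosis genes rose, with a median of 2.76. Genes of DNA repair, of the interferon response and of myeloid cells were also mostly higher. In contrast, 28 of 35 genes of the secretory pathway, 18 of 21 smooth muscle markers and 18 of 21 endothelial markers fell. Probasin, the secretory protein whose promoter drives the transgene, fell 9.62-fold.

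Of 19935 genes tested, 10527 (52.8%) passed an adjusted p of 0.05, 4540 higher and 5987 lower in APT121. The median difference of all genes was -0.09, and list medians are given without subtracting it, so a median near -0.09 is that of a typical gene. Without the lower-expressed 50% of genes the balance turned, with 3770 higher and 3327 lower. The larger changes were mostly rises. At least 2-fold changes numbered 1143 rises and 389 falls, and at least 8-fold changes 130 rises and 29 falls. The 4 APT121 values and the 8 wild type values did not overlap for 6894 genes (34.6%), where chance gives 0.404%. Arrays of different genotype correlated at 0.944 to 0.957 (Pearson's r across genes, which are not independent replicates), arrays of the same genotype at 0.990 to 0.995. The first principal component held 78.4% of the variance and parted the genotypes, and the second, with 4.41%, parted wild type arrays 1 to 4 from wild type arrays 5 to 8. Without wild type arrays 5, 6 and 7, which carry fat or seminal vesicle transcripts described below, 9314 genes passed (a setting chosen after seeing the data), and without APT121 array 2, the lowest count among the 12 settings that leave out 1 array, 8979 passed.

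**Figure D1:**
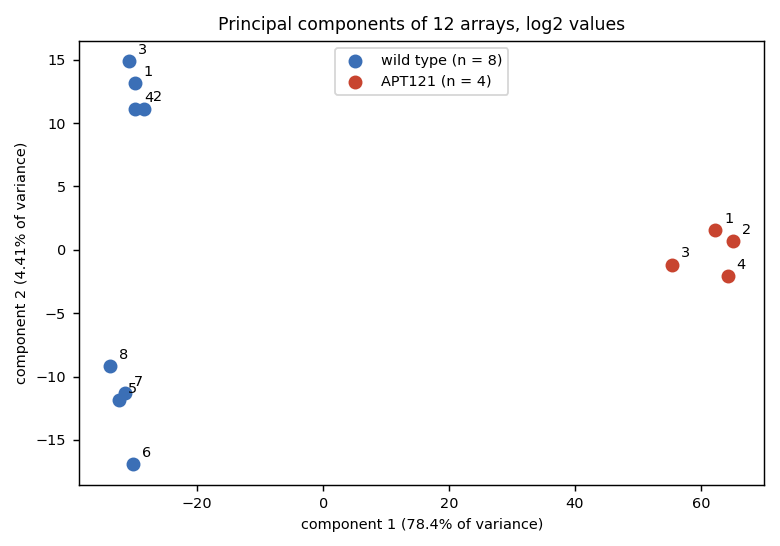
Principal components 1 and 2 of the log2 values of 12 arrays, with 1 point per array labelled by its replicate number. The 4 APT121 arrays sit at 55.5 to 65.1 on component 1 and the 8 wild type arrays at -33.8 to -28.4, and wild type arrays 1 to 4 sit above arrays 5 to 8 on component 2.

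The 10 largest measured rises among genes that separated the groups began with Psca. This gene (transcript cluster 10424662), which encodes a glycosylphosphatidylinositol-anchored surface protein first described in prostate, rose from 4.55 ± 0.40 to 10.97 ± 0.37, an 85.2-fold change (difference 6.41 ± 0.20, adjusted p = 5.39e-13). B4galnt2 (10390196), a glycosyltransferase that makes the Sd(a) antigen, rose 81.0-fold (6.34 ± 0.21, adjusted p = 1.06e-12), and Lrrc26 (10469984), an auxiliary subunit of the BK potassium channel, rose 53.1-fold (5.73 ± 0.21). Anpep, which encodes aminopeptidase N, rose by 5.48 ± 0.10. Slc12a2, the sodium-potassium-chloride cotransporter of secretory epithelia, rose by 5.36 ± 0.26, and Gabrp, a subunit of an epithelial chloride channel, by 5.21 ± 0.17. Atp13a4, a P-type ATPase, rose by 5.36 ± 0.12 and the metalloproteinase inhibitor Timp4 by 5.09 ± 0.11. The condensin subunit Ncaph (5.05 ± 0.14) and the chromatin remodeller Hells (4.89 ± 0.12) complete the 10. All 4 APT121 arrays lay above all 8 wild type arrays for each of them, as the naming rule required. For 8 of the 10 the wild type mean was below that of the median gene (5.38), and without detection calls such values were not shown to lie above background, so folds and ranks here are of measured intensities.

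The 10 largest measured falls were of genes with wild type means between 8.06 and 12.51, and for 6 of them the APT121 mean was below that of the median gene (5.44), with the same limit on folds and ranks. Pnliprp1 (10464313), a relative of pancreatic lipase, fell from 10.53 ± 0.17 to 3.98 ± 0.63, 94.1-fold lower in APT121 (-6.56 ± 0.19, adjusted p = 2.89e-13). Fgl1 (10578352), a fibrinogen-like secreted protein, was 49.7-fold lower (-5.64 ± 0.33, adjusted p = 7.81e-10), and Gsdma (10380976), a gasdermin, 45.9-fold lower (-5.52 ± 0.27, adjusted p = 9.16e-11). The fucosyltransferase Fut9 fell by 5.19 ± 0.28, the xylosyltransferase Gxylt2 by 4.65 ± 0.09 and the beta-galactosidase-like Glb1l3 by 4.86 ± 0.25. Mrgpra6, an orphan receptor, had a difference of -4.89 ± 0.18 and Mcoln3, an endolysosomal cation channel, one of -4.75 ± 0.22. The complement protease gene C1s2 (-4.64 ± 0.48) and Ms4a5 (-4.19 ± 0.27) were the others. The spread among APT121 arrays was wide for C1s2 (SD 1.78), Fgl1 (SD 1.15) and Fut9 (SD 1.02). All 4 of their values lay below all 8 wild type values, which the naming rule required.

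**Figure D2:**
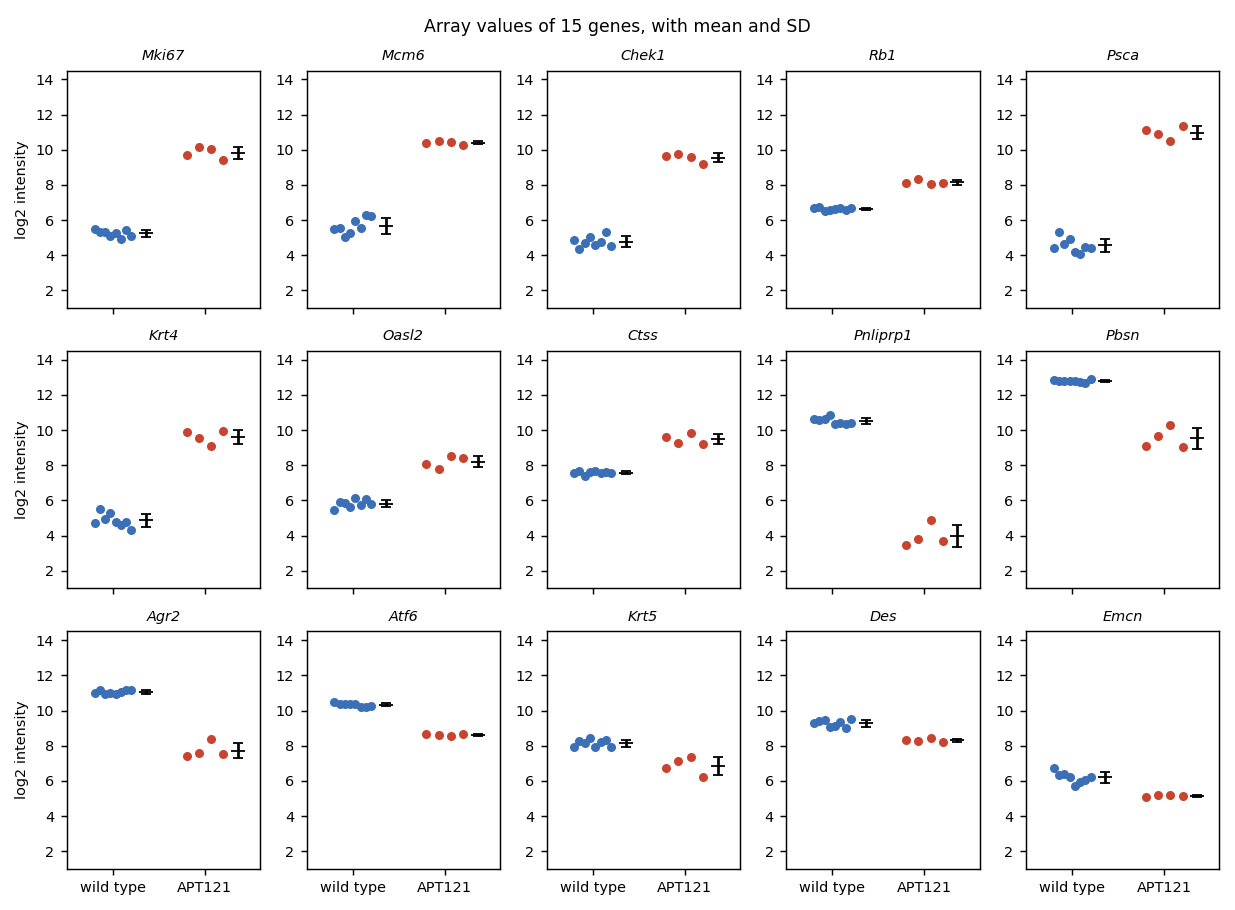
Log2 intensities of 15 genes in the 8 wild type arrays (blue) and 4 APT121 arrays (red), with 1 point per array in order of replicate number and black bars for the mean and SD. Mki67 lies at 9.82 ± 0.33 in APT121 and 5.23 ± 0.20 in wild type, and Pbsn at 9.53 ± 0.58 and 12.79 ± 0.07.

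Genes of DNA replication and E2F targets rose as a group. All 50 measured members passed the test in the same direction, also adjusted over the list alone. The replication licensing genes Mcm6 and Mcm3 rose by 4.74 ± 0.20 and 4.70 ± 0.13, Hells by 4.89 ± 0.12, and Pcna, the sliding clamp of the replication polymerases, by 2.50 ± 0.09 (adjusted p = 2.50e-12). The list passed camera (adjusted p = 2.61e-39) and held its call by a narrow margin (adjusted p = 0.04997 with an estimated correlation). Of the 60 mitosis genes, 58 rose and 0 fell, with the same counts adjusted over the list alone. Mki67, the antigen used to stain cycling cells, rose 24.0-fold (4.58 ± 0.13, adjusted p = 2.05e-13), Ncaph by 5.05 ± 0.14 and the cyclin gene Ccna2 by 4.16 ± 0.15. Pttg1 (-0.02) and Cks1b (-0.14) did not pass. Mitosis genes gave an adjusted p of 6.50e-42 by camera and an adjusted p = 0.0809 with an estimated correlation.

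The 30 measured genes of the pRb pathway and cell cycle entry moved both ways, with 17 higher, 5 lower and 8 not past the threshold, the same adjusted over the list alone. E2f8, an atypical E2F repressor, rose by 3.64 ± 0.11, the CDK inhibitor gene Cdkn2c by 2.77 ± 0.19 and cyclin E2 (Ccne2) by 2.46 ± 0.11. Within the pRb family itself, Rb1 rose 2.87-fold (1.52 ± 0.07, adjusted p = 3.42e-11) and Rbl1, which encodes p107, rose 5.12-fold (2.36 ± 0.13, adjusted p = 2.44e-10). Rbl2, which encodes p130, differed by -0.16 ± 0.08 (adjusted p = 0.0967) and passed when each array was centred on its median (-0.21, adjusted p = 0.0405) or quantile normalised again (-0.25, adjusted p = 0.00909). Cdkn2a, the tumour suppressor locus of p16 and p19ARF, differed by -0.02 ± 0.08 (adjusted p = 0.855; 95% interval -0.18 to 0.15). The members that fell were Ccnd1 (-1.26), Ccnd2 (-0.82), Cdk6 (-0.53), Ccnd3 (-0.39) and Myc (-0.29), of which the 3 cyclins and Cdk6 act upstream of pRb. The list passed camera (adjusted p = 4.46e-05) and also with an estimated correlation (adjusted p = 0.04997), and did not pass without the lower-expressed 50% of genes (adjusted p = 0.184).

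DNA damage response and repair genes were higher for 30 of 32 members and lower for 1, Xrcc5 (-0.16), with the same counts over the list alone. The checkpoint kinase gene Chek1 rose 27.4-fold (4.78 ± 0.16, adjusted p = 9.55e-13), and the homologous recombination genes Brca1 and Brca2 rose by 3.39 ± 0.08 and 3.11 ± 0.10. The list median was 1.48 and its adjusted p was 2.93e-20 by camera (adjusted p = 0.04997 with an estimated correlation). Of 28 measured p53 targets, 13 rose, 4 fell and 11 did not pass, unchanged over the list alone, with a median of 0.12. Plk2 (1.84 ± 0.16), Btg2 (1.83 ± 0.12) and the translesion polymerase gene Polk (1.33 ± 0.09) rose, while Mdm2 (-0.40), Bbc3 (-0.46), Phlda3 (-0.37) and Sesn2 (-1.07) fell. The p53 list passed camera (adjusted p = 0.0302; adjusted p = 0.0946 with an estimated correlation), and its call was lost without APT121 array 4 (adjusted p = 0.0520), after quantile normalisation (adjusted p = 0.0992) and without the lower-expressed 25% or 50% of genes (adjusted p = 0.117 and 0.224). Apoptosis genes were higher for 14 of 25 and lower for 6, the same over the list alone. Casp2, an initiator caspase, rose by 2.21 ± 0.07, the anti-apoptotic Bcl2l1 by 1.40 ± 0.09 and the apoptosome gene Apaf1 by 1.20 ± 0.09. The list passed camera (adjusted p = 0.00256; adjusted p = 0.102 with an estimated correlation), and not without the lower-expressed 50% of genes (adjusted p = 0.0663).

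Genes under androgen control and prostate secretory genes split. Of 25 androgen-regulated genes, 13 rose and 9 fell, also over the list alone, and the list did not pass camera (adjusted p = 0.140). Msmb, a secreted beta-microseminoprotein, rose by 4.74 ± 0.95 from a wild type mean that varied widely (8.67 ± 2.29) to 13.40 ± 0.15 (adjusted p = 5.73e-04), and the immunophilin Fkbp5 rose by 3.35 ± 0.15. Pbsn fell by 3.27 ± 0.17 (adjusted p = 1.48e-10) and the serine protease gene Tmprss2 by 1.85. Prostate secretory proteins were higher for 10 of 28 genes and lower for 10 (11 lower adjusted over the list alone), with a median of -0.17 and a mean of 0.42 (adjusted p = 0.612). Psca, Msmb, Sprr1a (3.60) and the serine protease inhibitor Spink5 (3.22) rose, and Gsdma, Pbsn and the transglutaminase Tgm4 (-2.74), a main protein of the secretion, fell.

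Genes of the secretory pathway and the unfolded protein response fell. Of 35 measured, 28 were lower and 2 higher (3 higher and 28 lower adjusted over the list alone), with a median of -0.59 (adjusted p = 2.87e-07; adjusted p = 0.102 with an estimated correlation). Atf6, a sensor of the endoplasmic reticulum, was 3.27-fold lower (-1.71 ± 0.06, adjusted p = 4.04e-12), and the resident proteins Creld2 and Dnajb9 differed by -1.48 ± 0.16 and -1.39 ± 0.09. Xbp1 (0.45) and Creb3l4 (0.53), transcription factors of secretory cells, were the members that rose.

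Energy and lipid metabolism changed gene by gene. Among 16 glycolysis genes, 4 rose and 5 fell, the same over the list alone, with a median of -0.05 and a mean of 0.21 (adjusted p = 0.904). Hexokinase Hk2 rose 11.1-fold (3.47 ± 0.19, adjusted p = 2.46e-10) and phosphofructokinase Pfkm fell by 1.40 ± 0.07. Pfkfb3 (1.30 ± 0.43, adjusted p = 0.0179) lost its call without APT121 array 2 (adjusted p = 0.0934) or array 4 (adjusted p = 0.0667), against wild type arrays 5 to 8 alone (adjusted p = 0.140), with array weights (adjusted p = 0.0792) and with the trend and robust options of eBayes (adjusted p = 0.0577). Oxidative phosphorylation genes were higher for 2 of 36 and lower for 16, also over the list alone (median -0.14, adjusted p = 0.0940). That list passed after quantile normalisation (adjusted p = 0.00700), without the lower-expressed 50% of genes (adjusted p = 0.0298) and against wild type arrays 5 to 8 alone (median -0.18, adjusted p = 0.0123), and not against arrays 1 to 4 (median -0.02, adjusted p = 0.445). The complex I subunit genes Ndufa1 (-1.61 ± 0.08), Ndufa2 (-0.96 ± 0.12) and Ndufb9 (-0.70 ± 0.07) fell. Lipid and cholesterol synthesis genes rose for 10 of 24 and fell for 5 (11 and 5 over the list alone; adjusted p = 0.101), with Srebf1, the regulator of fatty acid synthesis, up by 1.21 ± 0.17 and the desaturase Scd2 by 1.03 ± 0.12. This list passed against wild type arrays 1 to 4 alone (adjusted p = 0.00121) and without arrays 5, 6 and 7 (adjusted p = 0.00501), and not against arrays 5 to 8 alone (adjusted p = 0.570, a setting chosen after seeing the data). Stard4, a cholesterol carrier, rose by 1.05 ± 0.34 against all 8 arrays (adjusted p = 0.0158) and by 1.78 against arrays 5 to 8, while it differed by 0.32 against arrays 1 to 4 (adjusted p = 0.0687) and by 0.60 without arrays 5, 6 and 7 (adjusted p = 0.0791). Leaving out APT121 array 2 (adjusted p = 0.0529) and the trend and robust options (adjusted p = 0.0512) also ended its call. Polyamine, citrate and zinc metabolism genes rose for 4 of 16 and fell for 7 (5 and 7 over the list alone; median -0.19, adjusted p = 0.187), with falls of the isocitrate dehydrogenase Idh1 (-1.39 ± 0.11) and the metallothioneins Mt1 (-1.34 ± 0.10) and Mt2 (-1.28 ± 0.12). For vitamin D signalling, 5 of 13 genes rose and 2 fell, also over the list alone, with a median of -0.04 as deposited and 0.03 after quantile normalisation and a mean of 0.19 (adjusted p = 0.403). Cyp27a1, a sterol 27-hydroxylase, rose 5.32-fold (2.41 ± 0.10), the receptor gene Vdr 2.05-fold (1.03 ± 0.12, adjusted p = 3.21e-06), and Tgfb2 fell by 1.44 ± 0.11.

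Interferon response genes and markers of myeloid cells were higher in APT121. Of 26 interferon response genes, 21 rose and 1, Mx1 (-0.36), fell, also over the list alone, with a median of 0.94 (adjusted p = 6.56e-10; adjusted p = 0.102 with an estimated correlation). The antiviral gene Oasl2 rose 5.23-fold (2.39 ± 0.14, adjusted p = 5.58e-10), the immunoproteasome gene Psmb8 4.93-fold (2.30 ± 0.12) and the RNA sensor gene Ddx58 3.41-fold (1.77 ± 0.08). Myeloid markers rose for 19 of 27 genes and fell for 2, S100a8 and Cd163 (both -0.27), with the same counts over the list alone and a median of 0.58 (adjusted p = 1.06e-04; adjusted p = 0.335 with an estimated correlation). Cathepsin S (Ctss) rose by 1.91 ± 0.10, Laptm5 by 1.27 ± 0.12 and the Fc receptor chain gene Fcer1g by 1.07 ± 0.20. Lymphocyte markers rose for 6 of 22 genes and fell for 3 (5 and 3 over the list alone; adjusted p = 0.403), with a median of -0.05 as deposited and 0.05 after quantile normalisation and a mean of 0.17. The transcription factor Ikzf1 (2.12 ± 0.09), the T cell receptor chain Cd3g (1.59 ± 0.13) and Il2rb (1.01 ± 0.08) rose. Of 9 genes of antigen presentation by MHC class II, 2 rose and 1 fell, also over the list alone (adjusted p = 0.187). These were Ctss, Cd74 (0.43 ± 0.14, adjusted p = 0.0191) and Ciita (-0.21 ± 0.07, adjusted p = 0.0203), of which neither passed after quantile normalisation (0.28, adjusted p = 0.171, for Cd74 and -0.12, adjusted p = 0.188, for Ciita), against wild type arrays 1 to 4 (adjusted p = 0.0932 and 0.0546) or 5 to 8 (adjusted p = 0.0654 and 0.0641), or without wild type arrays 5, 6 and 7 (adjusted p = 0.0687 and 0.0740). Cd74 was at 8.58 in APT121 array 3 and at most 7.79 in the other 3, and without array 3 its difference was 0.20 (adjusted p = 0.0491), while Ciita did not pass without APT121 array 2 (adjusted p = 0.0884) or array 4 (adjusted p = 0.0644). Immediate early and heat shock genes, which respond to handling of tissue as well as to growth factors, rose for 11 of 21 and fell for 5, the same over the list alone, led by Egr1 (2.13 ± 0.13), Btg2 and Fosl2 (1.79 ± 0.14). That list (median 0.47, adjusted p = 0.0130; adjusted p = 0.335 with an estimated correlation) did not pass after quantile normalisation (adjusted p = 0.0622) or without the lower-expressed 25% or 50% of genes (adjusted p = 0.0719 and 0.224).

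**Figure D3:**
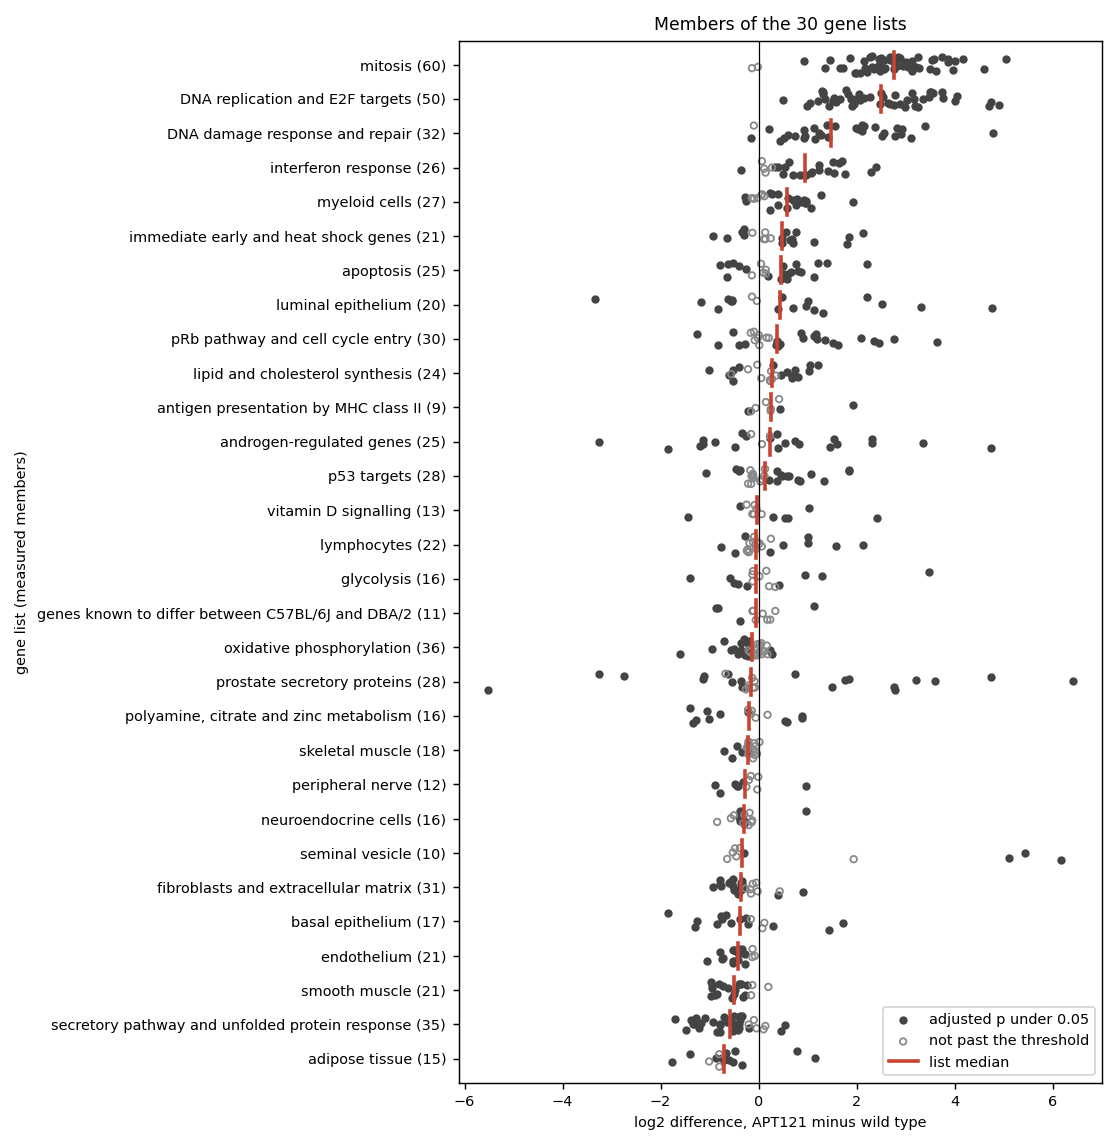
Log2 differences (APT121 minus wild type) of the measured members of 30 gene lists, with 1 point per gene, filled where the adjusted p is under 0.05, and a red bar at the list median. The medians run from -0.70 (adipose tissue) to 2.76 (mitosis).

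Epithelial markers changed in both directions. Luminal markers rose for 11 of 20 and fell for 7, also over the list alone (median 0.44, adjusted p = 0.0681, and 0.0346 with each array centred on its median and 0.0492 against wild type arrays 5 to 8). Keratin 4 (Krt4), a keratin of stratified epithelium, rose 26.9-fold (4.75 ± 0.19, adjusted p = 1.09e-11), the tetraspanin gene Tspan8 rose 9.92-fold (3.31 ± 0.18), and Krt8, the luminal keratin, rose 2.00-fold (1.00 ± 0.08, adjusted p = 2.96e-08). Agr2, a protein disulfide isomerase of secretory cells, was 10.1-fold lower (-3.33 ± 0.13, adjusted p = 9.65e-12). Basal markers fell for 11 of 17 and rose for 3, also over the list alone, with a median of -0.39 (adjusted p = 0.105). The basal keratin Krt5 fell by 1.29 ± 0.17 (adjusted p = 9.73e-06) and the laminin chain gene Lama3 by 1.85 ± 0.16, while the integrin genes Itga3 (1.72 ± 0.11) and Itgb4 (1.43 ± 0.10), which other epithelial cells also express, rose. Neuroendocrine markers were higher for 1 of 16 and lower for 6 (0 and 1 over the list alone; adjusted p = 0.113). The list median was -0.12 against wild type arrays 1 to 4 (adjusted p = 0.445) and -0.45 against arrays 5 to 8 (adjusted p = 0.00480). Gap43 (0.96 ± 0.35), Eno2 (-0.41 ± 0.16) and Chga (-0.39 ± 0.14) were near the threshold, and each lost its call without APT121 array 2 (adjusted p = 0.0820, 0.0619 and 0.109). Leaving out any of wild type arrays 1 to 4 or APT121 arrays 1 or 4 also ended the call of Gap43, leaving out wild type array 6, 7 or 8 or APT121 array 1, 3 or 4 that of Eno2, and leaving out wild type array 4, 6 or 7 or APT121 array 3 or 4 that of Chga, with adjusted p-values of 0.0502 to 0.103. Gap43 was itself 1.31 higher in wild type arrays 5 to 8 than in arrays 1 to 4 (adjusted p = 0.0226), and its difference was 1.62 against arrays 1 to 4 and 0.30 against arrays 5 to 8 (adjusted p = 0.359). Against arrays 1 to 4, Eno2 differed by -0.21 (adjusted p = 0.0739) and Chga by -0.26 (adjusted p = 0.140), and without arrays 5, 6 and 7 by -0.34 (adjusted p = 0.0618) and -0.26 (adjusted p = 0.116). After quantile normalisation the 3 genes had adjusted p-values of 0.0676, 0.110 and 0.0673, and Gap43 did not pass with the trend and robust options (adjusted p = 0.0817) or by exact permutation (p = 0.0586).

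Markers of the stroma were mostly lower in APT121. Smooth muscle markers were lower for 18 of 21 and higher for 0 (1 higher and 18 lower over the list alone), with a median of -0.51 (adjusted p = 5.93e-05; adjusted p = 0.335 with an estimated correlation). Desmin (Des) fell by 0.97 ± 0.09, tropomyosin Tpm2 by 0.96 ± 0.11, the gamma-actin gene Actg2 by 0.96 ± 0.12 and the alpha-actin gene Acta2 by 0.39 ± 0.08 (adjusted p = 4.44e-04). Fibroblast and extracellular matrix genes fell for 22 of 31 and rose for 2 (3 higher and 23 lower over the list alone), with a median of -0.37 (adjusted p = 0.00357; adjusted p = 0.377 with an estimated correlation). Decorin (Dcn) differed by -0.93 ± 0.15 and Igf1 by -0.79 ± 0.13, and the metalloproteinase inhibitor Timp1 rose by 0.90 ± 0.13. Endothelial markers fell for 18 of 21 and rose for 0, also over the list alone, with a median of -0.43 (adjusted p = 1.06e-04; adjusted p = 0.0934 with an estimated correlation), among them endomucin (Emcn, -1.06 ± 0.14), the VEGF receptor gene Kdr (-0.80 ± 0.09) and endoglin (Eng, -0.76 ± 0.09). Peripheral nerve markers fell for 6 of 12 and rose for 1, also over the list alone (median -0.29, adjusted p = 0.183). Prph (-0.89 ± 0.27, and -0.36 against wild type arrays 1 to 4, -1.42 against arrays 5 to 8 and -0.59 without arrays 5, 6 and 7) and the myelin gene Pmp22 (-0.79 ± 0.10) fell and Erbb3 (0.96 ± 0.09), which epithelium also expresses, rose. Skeletal muscle markers fell for 6 of 18 and rose for 0 (5 over the list alone; median -0.21, adjusted p = 0.0833), with falls of Acta1 (-0.72 ± 0.09), Tnnc2 (-0.55 ± 0.12) and Ckm (-0.44 ± 0.11). Adipose markers fell for 10 of 15 and rose for 2 (11 and 2 over the list alone; median -0.70, adjusted p = 0.0822, and 0.0264 without wild type array 1). Car3 (-1.77 ± 0.43) and Fabp4 (-1.41 ± 0.35) fell and the triglyceride synthesis gene Dgat2 rose (1.14 ± 0.31, and 0.69 with adjusted p = 0.0545 against wild type arrays 5 to 8), while wild type arrays 5 and 7 held the highest values of the brown fat genes Ucp1 (5.79 and 6.84) and Cidea (5.82 and 6.32), against at most 4.77 and 4.28 in the other 10 arrays. These 3 lists passed against wild type arrays 5 to 8, with medians of -0.43 for nerve, -0.23 for skeletal muscle (both adjusted p = 0.0492) and -0.97 for adipose tissue (adjusted p = 0.00637), and not against arrays 1 to 4, with -0.18, -0.12 and -0.39 (adjusted p = 0.301, 0.135 and 0.110).

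Seminal vesicle markers gave a mixed picture, in which 3 of 10 rose and 1 fell, also over the list alone, with a median of -0.34 and a mean of 1.59 (adjusted p = 0.498). Svs2, which encodes an abundant seminal vesicle secretory protein, rose by 6.17 ± 1.26 (adjusted p = 6.95e-04), Pate4 by 5.43 ± 1.23 (adjusted p = 0.00155) and Svs5 by 5.10 ± 1.14 (adjusted p = 0.00145). Wild type array 6 differed from the other wild type arrays in this list. It held Svs2 at 12.93, where the other 7 wild type arrays had 5.02 ± 0.81 (SD) and the APT121 arrays 12.19 ± 1.53, and it held Svs3a at 6.45, where the other wild type arrays had 2.57 ± 0.19 and the APT121 arrays 2.57 ± 0.24. Without wild type array 6 the differences were 7.16 for Svs2, 6.35 for Pate4 and 5.98 for Svs5.

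**Figure D4:**
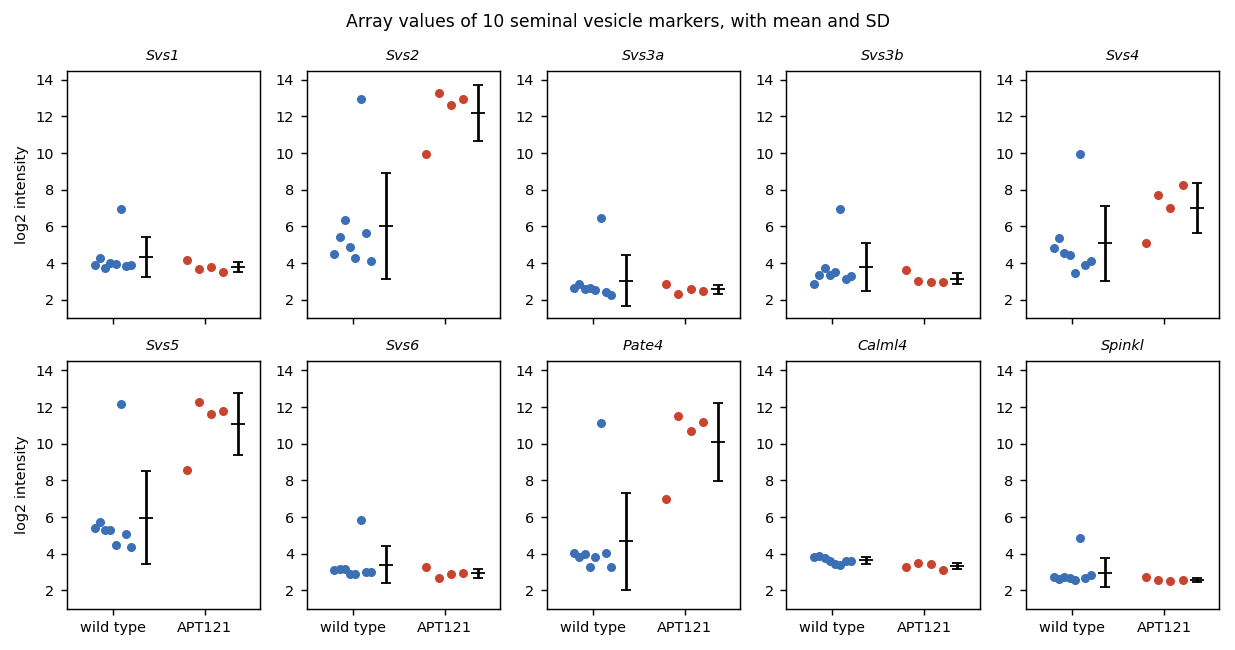
Log2 intensities of 10 seminal vesicle markers in the 8 wild type arrays (blue) and 4 APT121 arrays (red), with 1 point per array in order of replicate number and black bars for the mean and SD. Wild type array 6 is high for 9 markers, and the APT121 arrays are high for Svs2, Svs5 and Pate4 and 3 of them for Svs4.

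Genes known to differ between the parental strains C57BL/6J and DBA/2 had no common direction. Of 11, 1 rose and 3 fell, also over the list alone (median -0.06, adjusted p = 0.988), and 7 did not pass. Such genes can differ in either direction, so a median and camera cannot show whether parental background differed between the groups. Tested by fry without regard to direction, the list had an adjusted p of 1.36e-12, but so small a value was also found for lists such as glycolysis (4.66e-12). Myo5a rose by 1.13 ± 0.09, and Glo1 and Entpd4 differed by -0.86 ± 0.16 and -0.84 ± 0.09.

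Of the 30 lists, 13 passed camera, 9 higher and 4 lower in APT121, and 3 passed with an estimated correlation. In an exact two-sided permutation test of each list's median less the median of all genes over the 495 splits of the arrays, chosen after seeing the data, 20 lists passed, 13 higher and 7 lower, including all 13 that passed camera. Its smallest possible p of 0.00202 gives an adjusted p of 0.00433, reached by 11 of the 13, and the p53 targets and the fibroblast list had an adjusted p of 0.0114. The lists that passed this test and not camera were androgen-regulated genes, luminal and basal epithelium (each adjusted p = 0.00433), lipid and cholesterol synthesis and MHC class II (both 0.0135), skeletal muscle (0.016) and adipose tissue (0.0273). With 52.8% of genes changed, many gene sets pass this permutation test, so a pass does not set a list apart from other gene sets.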

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

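Apart from the exact permutation test of Svs2, the tests weighed here were chosen after the result was seen. Of 222 groups of array values (111 named genes in 2 genotypes), 9 held 1 array whose gap to its nearest neighbour, as a share of the group's range, passed Dixon's 95% critical value, where chance gives about 1 in 20. Wild type array 6 accounted for Svs2 (12.93 against 5.02 ± 0.81 (SD) in the other 7 arrays, ratio 0.747), Pate4 (11.14 against 3.75 ± 0.34, ratio 0.901), Svs5 (12.15 against 5.09 ± 0.50, ratio 0.823) and the glycolytic regulator Pfkfb3 (7.85 against 6.02 ± 0.24, ratio 0.742). Wild type array 3 was low for Idh1 (9.80 against 10.39 ± 0.11, ratio 0.612) and Fcer1g (5.01 against 6.01 ± 0.18, ratio 0.644). Wild type array 1 was low for Tspan8 (7.33 against 8.36 ± 0.21, ratio 0.611) and Car3 (6.78, against a spread of 0.39 (SD) among the other arrays, ratio 0.575). APT121 array 3 was high for Psmb8 (8.28 against 7.80 ± 0.03, ratio 0.902). Outside the gene tests, 2120 of the 7035 transcript clusters with several gene symbols or none differed between the genotypes by limma, 759 higher and 1361 lower in APT121.

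Secretory genes Svs2, Svs5 and Pate4 were high in all 4 APT121 arrays and in wild type array 6, yet the arrays differed in the rest of the seminal vesicle list, of which 0 of 10 members belong to another list and 0 have a mean over the 7 other wild type arrays above that of the median gene. In wild type array 6, 9 of the 10 markers lay above all 7 other wild type arrays, among them Svs2, Svs5 and Pate4 at 12.93, 12.15 and 11.14, which fits the seminal vesicle as a candidate source of RNA in that pool. In APT121 the other 7 markers had a median difference of -0.11 from those 7 wild type arrays, where wild type array 6 had 3.01, which argues against seminal vesicle tissue as the source of Svs2, Svs5 and Pate4 in the APT121 pools. The exception among the 7 was Svs4, which was 2.63 higher in APT121, with 3 of 4 arrays above those 7 wild type arrays, and 5.57 higher in wild type array 6, while the others differed by -0.34 to 0.0033 in APT121. The APT121 arrays varied in step, and array 1 was the lowest for Svs2 (9.93), Svs5 (8.59), Pate4 (6.98) and Svs4 (5.12). The other APT121 arrays held at least 12.61, 11.62, 10.70 and 6.98 of these. Why pools of the same genotype varied so was not tested. A change of Svs2, Svs5 and Pate4 in the prostate cells of APT121 mice stays open (exact permutation p = 0.00606 for Svs2), since no values per cell type decide it.

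Wild type arrays 1 to 4 and 5 to 8 differed by 325 genes, 119 higher and 206 lower in 5 to 8. The highest of the other splits of the 8 arrays gave 1, and 1 of 35 splits reached the real count. Principal component 2 of the same values parts arrays 1 to 4 from 5 to 8, and the split was tested after that was seen. The real split was thus likely to give the highest count, so this test cannot exclude chance. By camera 9 lists were higher in 5 to 8 and 0 lower, namely lipid synthesis (median 0.36, adjusted p = 1.57e-13), neuroendocrine cells (0.31, adjusted p = 4.56e-09), oxidative phosphorylation (0.10, adjusted p = 9.85e-06), adipose tissue (0.58, adjusted p = 1.41e-04), glycolysis (0.14, adjusted p = 5.80e-04), DNA replication (0.10, adjusted p = 7.83e-04), polyamine, citrate and zinc metabolism (0.11, adjusted p = 0.00391), peripheral nerve (0.20, adjusted p = 0.00428) and fibroblasts (0.05, adjusted p = 0.0384), and 0 passed with an estimated correlation (adjusted p = 0.330 to 0.537). Nerve or fat tissue in pools 5 to 8 is argued against for the 206 lower genes, whose smallest fall was -0.30, since tissue that dilutes the prostate would lower the luminal list too, and its median was 0.02 (-0.0872 when 2 standard errors are taken off). It might account for higher genes, of which the adipose, nerve and neuroendocrine lists (15, 12 and 16 genes measured) hold 6 of 119. These were Uchl1, Gap43, Snap25, Syp, Prph and Nefm, all from the nerve or neuroendocrine lists. Over all 19935 genes tested, 119 were called higher, a smaller share. Lists this short cannot account for most of the 119, so the source of the higher genes stays undecided. Other genes known from neurons, picked after their values were seen, were also higher in 5 to 8, such as Stmn2 (1.86, adjusted p = 0.00190), Npy (1.54), Htr3a (1.49), Tubb3 (0.94), Dbh (0.92), Chrna3 (0.89), Th (0.84), Slc18a2 (0.79) and Vip (0.52). The largest differences of the 325 were those of Gm5087 (-3.19), Nudt10 (-2.16), Cd59a (-1.96) and Nudt11 (1.90), none from the adipose, nerve or neuroendocrine lists. Nudt10 and Nudt11, both on the X chromosome, differed in opposite directions. Inherited blocks of parental sequence could place called genes side by side, and 49 had a called neighbour within 3 genes, more than in 99.3% of random lists (median 30), but the same number of top genotype genes gave 45 (96.8%), so this cannot be told apart from ordinary clustering of genes, and a processing batch likewise stays open for the 325 genes, as no batch label was given.

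Smooth muscle, fibroblast and endothelial markers were lower in APT121, with medians of -0.51, -0.37 and -0.43. A normalisation that lowers all unchanged genes would lower random lists of like expression too, and each median lay at or below the 0.02 percentile of 10000 such lists. These were drawn gene by gene from all genes, rising ones included, and do not allow for markers that vary together. Camera with an estimated correlation gave an adjusted p of 0.335, 0.377 and 0.0934, so the percentiles alone do not exclude such a normalisation. A smaller share of stroma in the APT121 pools stays open. The list medians of markers above the median level were -0.53, -0.38 and -0.50 and differed by at most 0.15, or 1.10 standard errors, but single markers did not fall alike, and 24 of 60 lay over 2 standard errors from the median of their list, such as Des (-0.97) and Timp1, which rose (0.90). A change within stromal cells was not tested.

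Other splits of the arrays bear on the main counts. Of 100 splits of the 12 arrays into 4 and 8, only the real 1 called as many genes (10527, highest other 234). Chance is thus an unlikely account of the gene count, though 1 in 100 is the lowest share this test can give. A batch that divided the arrays by genotype cannot be told apart by such splits, and no batch label was given. The list count was reached by 28 of 100 splits (real 13, highest other 18), so by this count chance cannot be excluded for the number of lists that pass camera at its preset correlation. Of the 28, 25 held 0, 2 or 3 APT121 arrays among the 4, and such splits keep part of the genotype difference. List by list, 1 of the 495 splits, the real one, gave as large a median for 11 of the 13 lists (exact permutation). Many gene sets pass that test where 52.8% of genes differ by genotype, as 129 of the 327 symbol families described below did. It ties a list median to the genotype split and does not set the list apart from other gene sets.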

How the results depend on the processing

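Wild type arrays 5 to 8 alone, the omission of wild type arrays 5, 6 and 7, and the exact permutation of list medians were chosen after seeing the data. Apart from the 1.5-fold minimum given below, the count of changed genes (10527) stayed between 7097 (lower 50% of genes left out) and 14489 (SAM-type statistic). It was 8979 to 10493 when 1 array was left out. Without the lower 50% of genes, where fewer genes were tested, 3770 calls were higher and 3327 lower, so that higher calls became the majority (53.1% against 43.1%). The count of lower genes (5987) was 9052 by the SAM-type statistic (the cause was not tested). A 1.5-fold minimum left 3552 genes by construction. Median centring gave 34.4% of calls higher against 43.1%. Of 30 lists, 13 passed camera, 3 with an estimated correlation, 26 by fry, which does not compare a list with other genes, and 20 by exact permutation of the median, each a different test. No source used here says whether replicate numbers 1 to 4 pair the arrays. Correlations of deviations between arrays of the same number were 0.0403, 0.0440, 0.116 and -0.0135. Not every array correlated best with its own number, which does not decide whether the arrays were paired. With the replicate block 8814 genes passed, against 8899 on the same 8 arrays without it. Counting each named gene under each setting, 2595 results kept their side of the threshold, 55 lost it and 2 gained it, and 0 reversed. For lists 723 kept it, 19 lost it and 33 gained it. Lost calls were of Gap43, Eno2, Chga, Cd74, Ciita, Pfkfb3, Stard4 and Dgat2. Against wild type arrays 5 to 8, Dgat2 had an adjusted p of 0.0545. Array signal close to background limits genes of low intensity, whose differences are compressed.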

Other observations

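The tests here were chosen after the data were seen. Genes were also grouped by the letters that begin their symbols, leaving out broad stems such as Tmem, which gave 327 families of at least 8 tested genes. Of 20 nucleoporin genes (Nup), 16 were higher and 1 lower in APT121 (median 0.86, camera adjusted p = 3.74e-08), and the splicing families Srsf (7 of 10 higher, median 0.42, adjusted p = 0.0264), Sf (8 of 10, median 0.43, adjusted p = 0.00374) and Prpf (8 of 12, median 0.34, adjusted p = 0.0273) were higher too. The families named here, these and those that follow, had an adjusted p = 0.425 to 0.700 with an estimated correlation. The deadenylase subunits Cnot (9 of 11 higher, adjusted p = 0.00374) and the Integrator subunits Ints (11 of 15 higher, adjusted p = 0.0135) went the same way. Annexins (Anxa), calcium-dependent membrane proteins, were higher for 8 of 12 and lower for 3 (median 0.81, adjusted p = 0.0264). Collagen genes (Col), 9 of which are in the fibroblast list, were lower for 36 of 44 and higher for 0 (median -0.38, adjusted p = 3.09e-05), where the fibroblast, smooth muscle and endothelial lists had medians of -0.37, -0.51 and -0.43. The complex I families Ndufa (10 of 14 lower, median -0.36, adjusted p = 0.0264) and Ndufb (8 of 9 lower, median -0.37, adjusted p = 0.0478) were lower. Both share genes with the oxidative phosphorylation list, such as Ndufa1, Ndufa2 and Ndufb9, so they are not separate from it. In all, 29 families passed camera, 0 passed with an estimated correlation, and all 29 passed an exact permutation test of the family median over the 495 splits (129 families did). The permutation test adds no support for the 29, since it also passed families far from a camera call. Armc, for example, had a median of 0.05, a camera adjusted p of 0.817 and an exact permutation adjusted p of 0.00930.

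Some single genes, chosen after their values were seen, had large changes outside the fixed lists. The secreted chaperone Clu rose by 4.04 ± 0.24 (adjusted p = 6.57e-10), the transcription factor Klf5 by 3.48 ± 0.17 and the epithelial sodium channel subunit Scnn1a by 4.52 ± 0.24. The potassium channel gene Kcnk5 rose by 3.78 ± 0.10 and Fxyd3, a regulator of the sodium pump, by 4.27 ± 0.11. The cytochrome gene Cyp2f2 rose by 4.22 ± 0.29, and Mcoln2, the neighbouring relative of Mcoln3, fell by 3.89 ± 0.09.

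APT121 array 2 held a few transcripts far above the other 11 arrays. Ptgs2, the inducible cyclooxygenase, was at 10.07 there and at most 5.08 elsewhere, and Serpina1f was at 9.05 and at most 4.04. Slco2a1, a prostaglandin transporter, was at 8.59 and at most 7.05, Abcg2 at 7.32 and at most 4.97, and Ly6f at 6.25 and at most 4.51. Defb42, a beta-defensin gene, was at 7.08 there, at 6.07 in APT121 array 4 and at 5.60 in wild type array 6. Whether neighbouring tissue was part of that pool was not tested.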
